A study of Mus musculus with 8 samples.

How the data were processed

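Gene expression was measured with 1-colour Agilent arrays in 8 samples of primary spheres grown from mouse ganglion cells. Per the labels, the cells came from the superior mesenteric ganglion of 3-week-old mice hemizygous for TH-MYCN, a transgene that drives human MYCN in sympathetic cells and gives rise to neuroblastoma. Cells of each ganglion were split between medium with retinoic acid (RA) and medium without it, and spheres were collected after 8 days. The labels number 4 biological replicates in each medium, so 4 arrays were of RA-containing and 4 of RA-free cultures. Per the labels, 40 or 200 ng of total RNA with an integrity number over 8 was labelled with Cy3, and the amount is not tied to single arrays.

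Per the file headers, the authors scanned all 8 arrays of design 028005 on 1 slide in 1 scan and extracted spot intensities with Agilent Feature Extraction 11.5.1.1, with an annotation built on mm9. Per the file headers, the processed intensity is background-subtracted and detrended within each array and is not scaled between arrays. The deposited flags of spots well above background, saturated spots and outlier spots were also used. The authors also deposited a table of log2 values for 55821 probes. Set against the processed intensities of the same arrays, each of its columns was a log2 value scaled near the array's 75th percentile, with every probe centred on its mean over the 8 arrays. The lowest correlation with the scanner values was 0.9999 and over 99.5% of probes lay within 0.01 of a constant offset. The exact scaling behind these deposited log2 values stays unknown, while centring and direction are settled by the match. The column medians were −0.23, −0.22, 0.02 and −0.01 for RA-containing replicates 1 to 4, and −0.07, 0.01, 0.17 and 0.20 for RA-free replicates 1 to 4.

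Each array held 62976 spots, of which 59305 were not controls and covered 55681 probes. Outlier spots were left out, which removed 64 probes, and saturated spots would have been kept but none of the non-control spots was saturated. Processed intensities were taken to log2, the array's 75th percentile was subtracted and spots of one probe were averaged. Levels are therefore log2 values relative to the 75th percentile of the array. Probes were named through the accession in the scanner files and a RefSeq gene table of assembly GRCm38.p6, where 27235 probes matched 1 of 20660 symbols and 28446 matched none. The table and the array annotation rest on different builds, so no coordinates are given and the table served for names and gene order alone. Tested probes were well above background on at least 4 of the 8 arrays. For each symbol the probe with the highest mean over all 8 arrays was kept, which set aside 4309 probes and left 13538 genes. Where several probes of a named gene differed widely, both ends of their range are given, except for genes with only a bound and for Ramp1.

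The comparison was RA-free minus RA-containing medium, fitted with limma 3.58.1 in R 4.3.3 with the animal as a fixed block, two-sided, with Benjamini-Hochberg adjustment over all tested genes. Genes with an adjusted p under 0.05 are called changed. The pairing comes from the series' description of the cultures. It was checked on the deviations of arrays from their medium's mean: the correlations of the pairs of arrays numbered 1 to 4 were 0.52, 0.30, 0.19 and 0.33, and each array matched its own partner best. Different animals had a mean correlation of −0.11, which follows largely from the centring and adds no support. Without the block for the animal pairing, 8022 genes were called in place of 8705.

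A total of 16 gene lists were tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated from the residuals, and with fry, with adjustment over the lists. The lists were retinoic acid response, sympathoadrenal identity, pan-neuronal, cell cycle, MYC target and ribosome biogenesis, RXR and LXR targets, cholesterol synthesis, stem-cell and Notch, hypoxia and glycolysis, p53 response, unfolded protein and amino acid stress, and the markers of Schwann and satellite glia, fibroblasts, immune cells, endothelium and adrenal cortex. The fry test asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Mean levels of the 5 lists of other cell types were also compared by an exact two-sided sign-flip test over the 4 animals, whose smallest possible p is 0.125.

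Named genes were Mycn, Rarb, Cyp26a1, Cyp26b1 and Dhrs3, the 12 largest increases and 12 largest decreases among called genes that moved the same way in all 4 animals and were well above background on all arrays of the higher medium, and up to 4 called members of each list with the largest change. The lists, the naming rule, the tests and most alternatives were fixed before the data were examined. List members that are named because they went against their list were picked after their values were seen. Some genes that the rule names are not reported here. A gene with no probe well above background on any array of a medium has only a bound there. Its fold is then the mean level of the brighter medium over the mean, across the dimmer arrays, of the higher of the lowest level well above background and the probe's own level, and is written as at least that many fold, a bound that holds for the processed signal alone. The number of arrays limits the precision of all values.

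The alternatives were a fit without the block or with a random block, normexp (offset 50) with quantile normalization, quantile normalization of the processed intensities, a 75th percentile over probes above background on all arrays, no filter on dim probes or a filter on all 8 arrays, the mean of all probes of a gene, all probes, the deposited log2 table, an intensity trend in the variance, array weights, another threshold, and leaving out each animal in turn. The files hold the median rather than the mean spot brightness, so normexp was run on the median brightness and its local background. Slide and scan could not be blocks because all arrays shared 1 of each. Scaling by 7 spike-in probes, scaling by the median and the fits of animals 1 and 2 or 3 and 4 alone were added after the data were seen.

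The fit was tested on simulated data with the spread of the 13538 genes, where it recovered 37.9% of genes changed by 0.5, 85.1% of those changed by 1 and 86.6% of those changed by 2 on the log2 scale, and called 9 of 13338 unchanged genes. The simulation changed 66, 67 and 67 genes by these sizes, against 8705 called in the data, so its recovery rates need not hold there. In simulated data with the cell cycle list raised by 0.5 on the log2 scale, camera called that list and 0 of the other 15. The simulated noise was independent between genes, while the correlation estimated for the real cell cycle list was 0.70. The simulation therefore cannot test camera's preset correlation. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Spike-in probes enter no comparison of genes, and probes without a gene name enter only the alternative that counts all probes.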

Results

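Transcripts were measured in primary spheres from the superior mesenteric ganglion of TH-MYCN mice, with 4 arrays of RA-containing and 4 arrays of RA-free cultures, each pair from 1 animal. Of the non-control spots, 52.7% to 55.3% were well above background on the RA-containing arrays and 48.5% to 55.0% on the RA-free arrays. The 75th percentile of the processed signal was 302, 306, 228 and 299 intensity units on RA-containing arrays 1 to 4, and 295, 244, 262 and 235 on RA-free arrays 1 to 4, against a median local background of 26 to 29. The first principal component held 81.7% of the variance and separated the media. On it RA-free array 1 lay at 42.3 and the other RA-free arrays at 59.5 to 66.2; without animal 1, 7954 genes were called in place of 8705.

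The comparison of the media addresses how TH-MYCN ganglion spheres differ when retinoic acid is left out, the condition that the series describes as suited to growing these neuroblasts. Without RA, cell cycle genes were higher, with Birc5 5.0-fold and Cdk1 4.9-fold above their RA-containing levels. Genes of the RA response and many neuronal genes were lower: Dhrs3, which reduces retinaldehyde to retinol, was 32.0-fold lower, and Prph, the intermediate filament peripherin of peripheral neurons, was 36.7-fold lower. Th, the rate-limiting enzyme of catecholamine synthesis, was 12-fold higher (log2 change 3.59, SE 0.14, n = 4 animals). The mouse Mycn transcript had a log2 change of −0.18 (SE 0.11, adjusted p = 0.198 by limma) and was lower in 3 of 4 animals.

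Of 13538 genes tested, 8705 (64.3%) were called changed, 4885 higher and 3820 lower in RA-free medium. Under spike-in scaling 5463 were called, 2027 of them lower, and the share of called genes that were higher, 56.1%, ranged from 46.3% to 62.9% over the scalings. A change of at least 1 on the log2 scale was found for 1018 of the higher and 1437 of the lower genes, and of at least 2 for 195 and 533. The median change of all tested genes was 0.07 and the median size of a called change was 0.66. Of the called genes, 8614 (99%) changed the same way in all 4 animals, which the test itself favours. By any of their probes, 182 of the genes called lower were not well above background on any RA-free array, and 40 of those called higher were not on any RA-containing array.

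**Figure D1:**
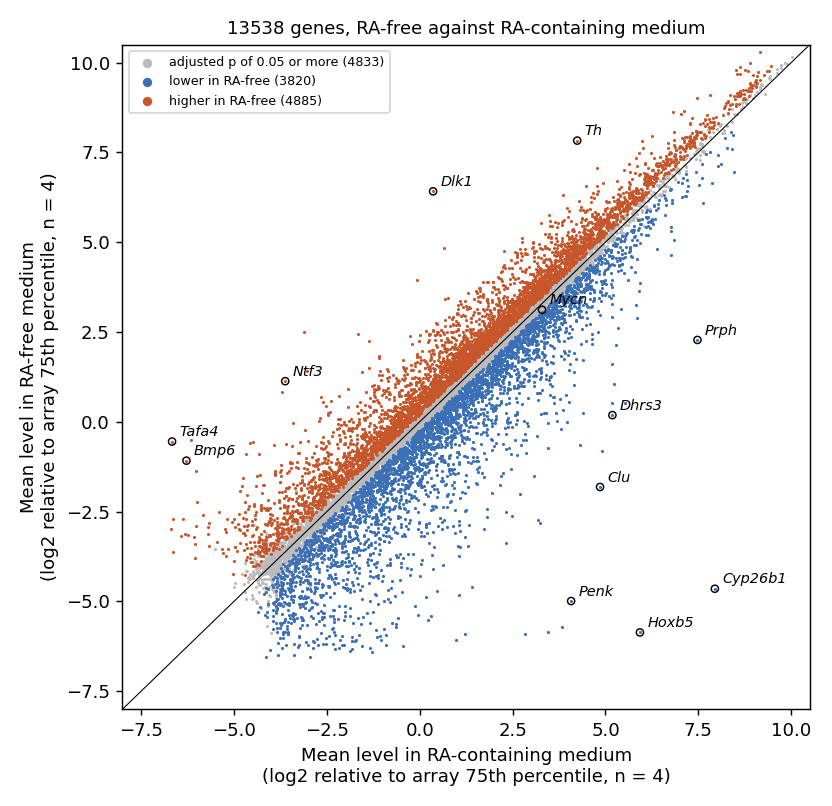
Mean level of each of the 13538 tested genes in RA-free medium against RA-containing medium (log2 relative to the array's 75th percentile, n = 4 arrays each). Orange points are the 4885 genes called higher and blue points the 3820 called lower; levels of genes not well above background, such as Hoxb5 in RA-free medium, are measured values below the detection limit.

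The largest increases included Dlk1, a membrane protein related to Notch ligands, whose level went from 0.36 ± 0.62 to 6.42 ± 0.62 (SD, n = 4), a 66.5-fold rise (adjusted p = 7.49e-05). Unc93a rose by 5.60 (SE 0.10), Ntf3, which encodes neurotrophin 3, by 4.75 (SE 0.18), Hhip, an antagonist of hedgehog ligands, by 4.43 (SE 0.21), and Anxa1 by 4.03 (SE 0.20). Tafa4, Bves and Bmp6 were not well above background on any RA-containing array and were at least 15.6-fold, 16.1-fold and 10.8-fold higher in RA-free medium. Under normexp with quantile normalization their changes of 1.99, 1.97 and 1.44 were smaller than these bounds. Among the largest decreases, Clu fell from 4.85 ± 0.36 to −1.81 ± 0.43 (adjusted p = 6.43e-05), Adra2a, an adrenergic receptor, had a change of −6.06 (SE 0.30) and Skap2 one of −5.92 (SE 0.13). Penk, the enkephalin precursor, Nckap1l, Hoxb6 and Frmpd4 were not well above background on any RA-free array and were at least 295-fold, 206-fold, 134-fold and 37.4-fold lower. Their changes of −5.76, −5.44, −4.80 and −3.15 under normexp with quantile normalization were smaller than these bounds. For Ramp1, a partner of the calcitonin receptor-like receptor, the brightest probe was not well above background on any RA-free array, while another probe stayed well above background on all arrays with a change of −1.64.

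Genes of the retinoic acid response were lower without RA, with 13 of 21 tested members called lower and 3 higher, and a median change of −1.43 (−0.40 with no filter on dim probes, which adds members near background). Cyp26b1, an enzyme that degrades RA, stood at 7.94 ± 0.06 with RA (SD, n = 4) and was called lower (adjusted p = 3.71e-05). It was well above background on 1 of 4 RA-free arrays, so its change, −12.59 in the fit and −9.82 under normexp with quantile normalization, has no exact size. Hoxb5 was at least 1148-fold lower. Its change of −8.32 under normexp with quantile normalization was smaller than this bound. Dhrs3 (NM_011303) fell from 5.19 ± 0.07 to 0.19 ± 0.22 (adjusted p = 2.35e-05), and Rarb (NM_011243), the RA receptor beta, from 4.36 ± 0.04 to 2.58 ± 0.18 (adjusted p = 8.31e-05), with changes of −1.86 and −1.77 for its probes. Hic1, also well above background on 1 of 4 RA-free arrays, had a change of −4.31, or −1.92 under normexp with quantile normalization. The members that rose were Meis2 (2.78, or 1.51 under normexp with quantile normalization), Meis1 (0.40, or 0.03 and not called under it) and Crabp2 (0.22); with spike-in scaling 1 member was called higher. Adjusted over the list alone, 14 members were lower and 3 higher. The list was called by camera (adjusted p = 0.000170), a call that was lost with an adjusted p = 0.331 with an estimated correlation, and fry gave an adjusted p of 0.000195. Cyp26a1 was not well above background on any array and was not tested.

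Cell cycle genes rose together: all 30 tested members were called higher, over all genes and adjusted over the list alone, with a median change of 1.89. Birc5, which acts in chromosome segregation and cell survival, rose from 4.76 ± 0.28 to 7.07 ± 0.28 (adjusted p = 6.40e-05), Cdk1, the mitotic kinase, from 1.29 ± 0.41 to 3.59 ± 0.51 (adjusted p = 9.52e-05), and Ccnb1 and Kif11 by 2.26 and 2.25. The list was called by camera (adjusted p = 1.93e-11; adjusted p = 0.459 with an estimated correlation, so the call was lost), and fry gave an adjusted p of 0.00207. Of the 28 tested MYC target and ribosome biogenesis genes, 26 were called higher and 2 lower, the same counts adjusted over the list alone, with a median change of 0.69. Odc1, which makes polyamines, rose by 1.29 (SE 0.07), Nop58, a part of small nucleolar ribonucleoproteins, by 1.16 (SE 0.10), Cdk4 by 1.16 (SE 0.08) and Id2 by 1.14 (SE 0.12). The members that fell were Ccnd2 (−0.58) and Tert (−0.53), with −0.28 and −0.21 under normexp with quantile normalization, neither of which passed under spike-in scaling. Camera called this list (adjusted p = 2.75e-05; adjusted p = 0.396 with an estimated correlation, so the call was lost), and fry gave an adjusted p of 0.00195. Mycn itself stood at 3.29 ± 0.16 with RA and 3.12 ± 0.17 without. It passed the test under normexp with quantile normalization (−0.29, limma adjusted p = 0.0210) and quantile normalization alone (−0.32, 0.0463), within a range of 0.0210 to 0.950 over the alternatives. The mouse probe need not detect the human transgene.

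**Figure D2:**
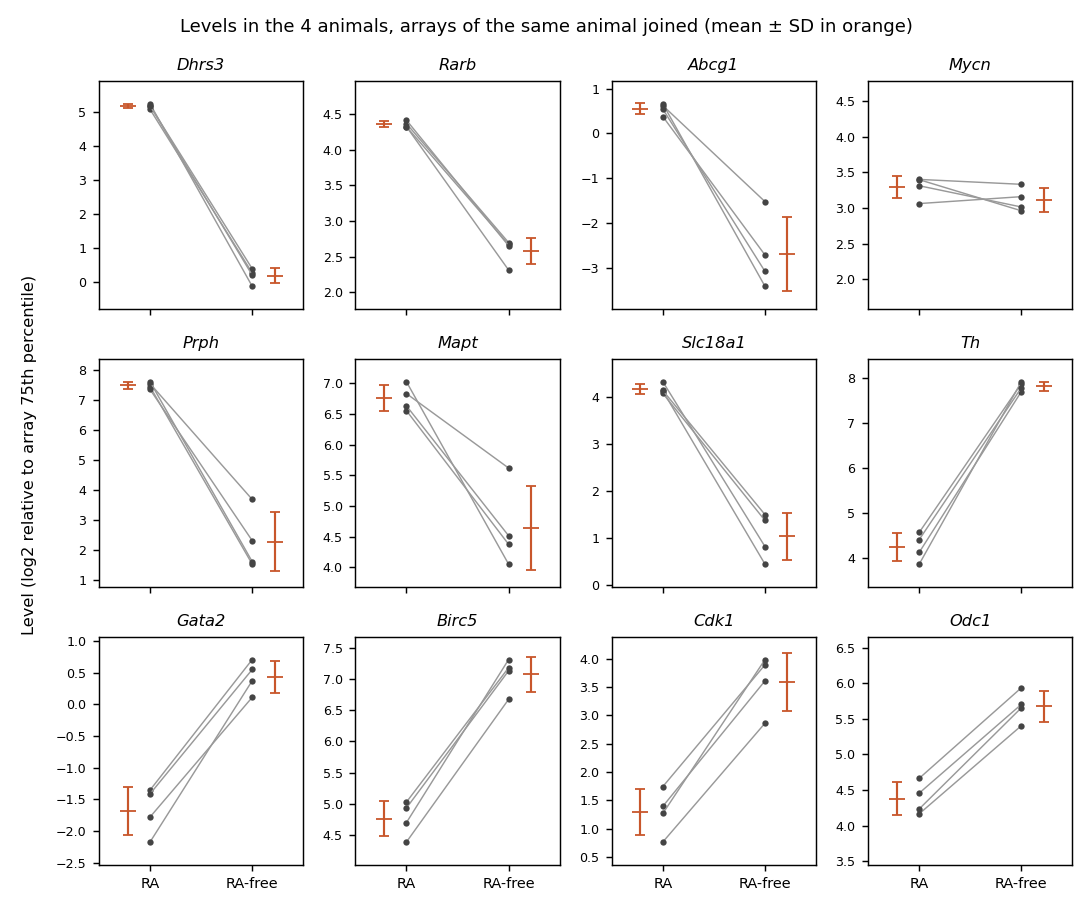
Levels of 12 named genes on each array (log2 relative to the array's 75th percentile), with arrays of the same animal joined and the mean ± SD of the 4 arrays of each medium in orange. Dhrs3, Rarb, Abcg1, Prph, Mapt and Slc18a1 were lower and Th, Gata2, Birc5, Cdk1 and Odc1 higher in RA-free medium in all 4 animals; Mycn was lower in 3.

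Neuronal genes were lower without RA, with 18 of 24 pan-neuronal members called lower and 1, Elavl4 (0.62, or 0.31 under normexp with quantile normalization), called higher, and the same counts adjusted over the list alone. Prph fell from 7.48 ± 0.11 to 2.28 ± 1.00 (SD, n = 4; adjusted p = 0.000180), and Mapt, the microtubule protein tau, had a change of −2.12 (SE 0.27). The median change was −0.59 (−0.98 under quantile normalization of the processed signal) and the list was called by camera (adjusted p = 3.89e-05; adjusted p = 0.396 with an estimated correlation, so the call was lost), with a fry adjusted p of 0.00243. Spike-in scaling left 10 members called lower. Sympathoadrenal genes went both ways: of 25 tested members 10 were called higher and 7 lower, the same counts adjusted over the list alone, with a median of 0.21 (0.07 under quantile normalization of the processed signal, 0.36 under spike-in scaling and 0.13 without animal 2). Th rose from 4.24 ± 0.31 to 7.83 ± 0.10 (adjusted p = 5.34e-05) and Gata2, a transcription factor of sympathetic development, by 2.11 (SE 0.13). Slc18a1, which loads monoamines into vesicles, had a change of −3.12 (SE 0.21) and Tbx2 one of −2.22 (SE 0.08). Camera did not call the list (adjusted p = 0.643), while fry gave an adjusted p of 0.0343.

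Targets of the RXR and LXR nuclear receptors were lower, with 11 of 14 tested members called lower, the same count adjusted over the list alone, and a median change of −0.67. Mylip, a ubiquitin ligase that degrades the LDL receptor, had a change of −3.80 (SE 0.09, with −2.71 by another probe), Abcg1, a cholesterol exporter, −3.24 (SE 0.31), Cpt1a, which admits fatty acids to mitochondria, −2.47 (SE 0.10), and Ucp2 −2.25 (SE 0.12). The list was called by camera (adjusted p = 0.000686; adjusted p = 0.459 with an estimated correlation, so the call was lost), with a fry adjusted p of 0.00276, and 6 members were called lower under spike-in scaling. Cholesterol synthesis genes had a median change of 0.16, with 7 of 18 called higher and 3 adjusted over the list alone. Without animal 1 the median was 0.08, and under quantile normalization of the processed signal 0.0066; 3 members were called higher without animal 2 and 4 without animal 1, 3 or 4. Idi1 and Msmo1 rose by 0.65 (SE 0.08) and 0.57 (SE 0.09), or 0.39 and 0.31 under normexp with quantile normalization. Fdps, also among the 7, turned negative under some other scalings, and with the 75th percentile of detected probes 3 members were called higher and 4 lower. Neither camera (adjusted p = 0.482) nor fry (adjusted p = 0.0620) called the list.

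Markers of Schwann and satellite glia were lower, with 8 of 16 tested members called lower and 1 higher, the same counts adjusted over the list alone, and a median change of −0.47 (−0.22 with no filter on dim probes and −0.28 under normexp with quantile normalization). Ngfr, the low-affinity neurotrophin receptor that sympathetic neurons also make, had a change of −2.39 (SE 0.13), Ncmap −1.35 (SE 0.16) and Prx, a protein of myelinating Schwann cells, −1.34 (SE 0.15). Pou3f1, a transcription factor of Schwann cells before myelination, rose by 1.28 (SE 0.22). Camera called the list (adjusted p = 0.0192; adjusted p = 0.396 with an estimated correlation, so the call was lost), with a fry adjusted p of 0.00298. The call was also lost under quantile normalization of the processed signal (adjusted p = 0.0690), without animal 1 (0.0623), under spike-in scaling (0.135) and with animals 3 and 4 alone (0.0815), within a range of 0.00363 to 0.135 over the alternatives. The mean of the 16 members differed by −0.54 ± 0.10 (SD, n = 4 animals; exact two-sided sign-flip p = 0.125, the smallest possible, and 0.156 after adjustment over 5 lists).

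Markers of other cell types that a dissociated ganglion could hold were measured in the same way. Tested were 16 of 25 listed fibroblast, 7 of 22 immune, 8 of 15 endothelial and 5 of 12 adrenocortical genes. Markers such as Ptprc and Cd14 (immune), Cdh5 and Tek (endothelium) and Cyp11a1 and Cyp11b1 (adrenal cortex) did not pass the filter on dim probes. The values below therefore describe the tested members alone. Of 16 tested fibroblast and mesenchymal genes, 4 were called higher and 5 lower, the same counts adjusted over the list alone, with a median of −0.09 that was 0.06 under spike-in scaling, −0.20 under quantile normalization of the processed signal and −0.17 without animal 4. Col1a2, a collagen chain, rose by 1.03 (SE 0.18), while Fap and Postn had changes of −1.74 (SE 0.25) and −1.11 (SE 0.13). Of 7 tested immune genes, 3 were called lower, the same count adjusted over the list alone, namely Itgam (−0.51, SE 0.11; −0.16 by another probe, which did not pass with an adjusted p = 0.216) and the macrophage genes Aif1 and Adgre1, which were not well above background on any RA-free array and were at least 1.43-fold and 1.39-fold lower (changes of −0.41 and −0.31 under normexp with quantile normalization, smaller than these bounds). The immune median was −0.07, but 0.08 under spike-in scaling, −0.24 without animal 2 and 0.04 without animal 3. Of 8 endothelial genes, Pecam1 was called lower (−0.34, SE 0.12, adjusted p = 0.0474) over all genes but not adjusted over the list alone, a call lost under 4 of 5 other scalings, and the median was −0.12, or 0.03 under spike-in scaling, −0.22 without animal 3 and −0.07 without animal 4. Of 5 adrenocortical genes, Fdx1 (0.70, SE 0.08) and Star were called higher, the same count adjusted over the list alone, with a median of 0.35 (0.16 under normexp with quantile normalization). Star was well above background on 2 of 4 arrays of each medium, and its change was 0.73, or 0.16 under normexp with quantile normalization. The calls of Star and Itgam were each lost under 1 of the 5 other scalings. Camera called none of these 4 lists (adjusted p = 0.482, 0.307, 0.577 and 0.332), while fry gave an adjusted p of 0.0343 for the immune and 0.0138 for the adrenocortical list, against 0.191 for fibroblasts and 0.620 for endothelium. Their mean levels differed by −0.20 ± 0.21 for fibroblasts (−0.04 with no filter on dim probes), −0.72 ± 0.17 for immune cells and 0.38 ± 0.12 for adrenal cortex (each exact two-sided sign-flip p = 0.125), and by −0.12 ± 0.33 for endothelium (exact p = 0.625). With Aif1 and Adgre1 at their bounds the immune mean was −0.17.

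**Figure D3:**
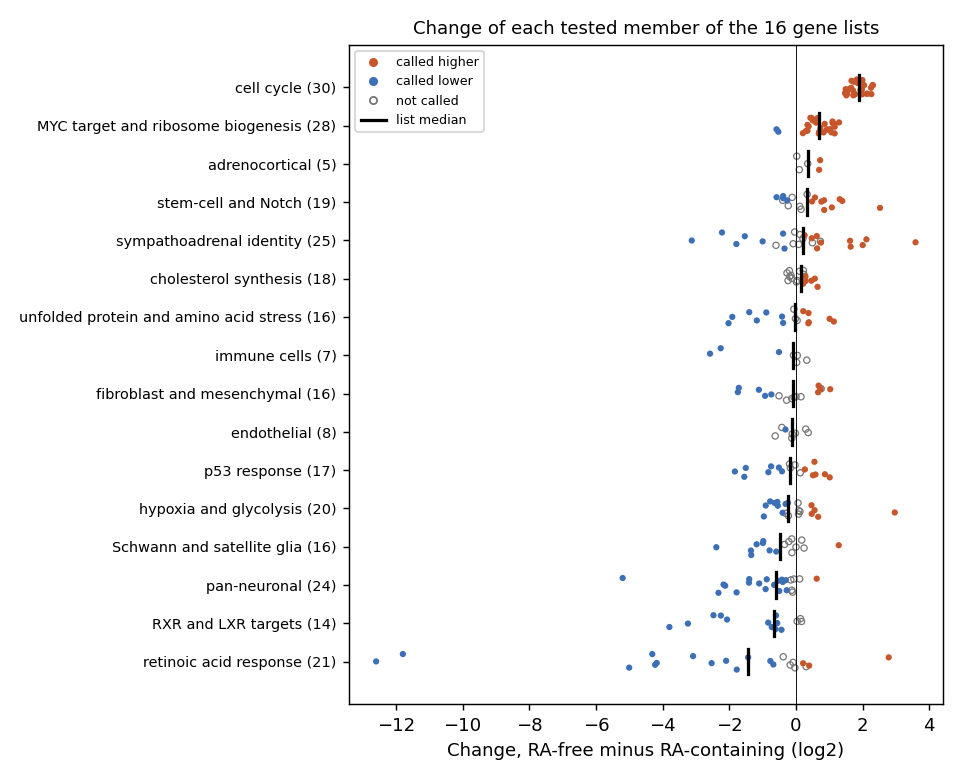
Change of each tested member of the 16 gene lists (log2, RA-free minus RA-containing, n = 4 animals), with called members filled, other members open and the list median as a black bar. The 30 cell cycle genes lie above 0, while the members of the sympathoadrenal, fibroblast and stress lists fall on both sides of it.

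The stem-cell and Notch list held 9 genes called higher and 4 lower among 19, the same counts adjusted over the list alone, with a median of 0.34, or 0.54 without animal 1. Under spike-in scaling the 4 lower genes did not pass. Kit, a receptor tyrosine kinase, rose by 2.52 (SE 0.18), Mdk by 1.39 (SE 0.07) and Hmga2 by 1.32 (SE 0.11). Of 20 hypoxia and glycolysis genes, 5 were called higher and 9 lower, the same counts adjusted over the list alone, and 3 were lower under spike-in scaling. Hk2, a hexokinase, rose by 2.96 (SE 0.17), while Pfkfb3 had a change of −0.96 (SE 0.10, with −0.64 by another probe) and Vegfa one of −0.77 (SE 0.08). Another probe of Vegfa, with −0.23, did not pass (adjusted p = 0.0541). The median of this list was −0.23 (−0.38 under quantile normalization of the processed signal and −0.08 under spike-in scaling), but its mean was 0.0036 with Adm, not well above background on any RA-free array, at its bound. The p53 response list had 6 members called higher and 7 lower among 17, the same counts adjusted over the list alone, with a median of −0.17 that was −0.07 without animal 3 and −0.01 under spike-in scaling, where 4 were lower. Gdf15 had a change of −1.83 (SE 0.13), Perp −1.50 (SE 0.10) and Aen 1.01 (SE 0.08). Among 16 genes of the unfolded protein and amino acid stress responses, 6 were called higher and 7 lower, the same counts adjusted over the list alone, with a median of −0.04 that was −0.34 under quantile normalization of the processed signal, 0.11 under spike-in scaling and −0.10 without animal 1. The 6 higher genes became 3 without animal 1, without animal 4 or under normexp with quantile normalization, and 2 under spike-in scaling. Trib3 and Chac1 had changes of −2.02 (SE 0.12) and −1.91 (SE 0.08), and Atf4 and Hspa5, among the higher genes, turned negative under some other scalings. Camera called none of these 4 lists (adjusted p = 0.332, 0.332, 0.412 and 0.332), while fry gave an adjusted p of 0.00543 for the stem-cell, 0.0401 for the hypoxia and 0.00298 for the stress list, against 0.0810 for p53.

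No list called by camera kept its call when the correlation between genes was estimated from these arrays. For the retinoic acid response and glial lists the estimated correlation, −0.0147 and 0.00583, was below the preset 0.01. A higher correlation between genes therefore cannot explain the lost calls of these lists. The arrays of the RA-containing cultures lay in columns 1 and 3 of the slide and those of the RA-free cultures in columns 2 and 4, so odd or even column and medium cannot be told apart. The normexp offset of 50 exceeds the median processed signal of the arrays (16.6 to 22.5), so changes of dim genes shrink under this alternative by construction. Under normexp with quantile normalization the change was smaller by more than 1.5 times in 22 of the 65 named genes that were called and have no bound, and larger by as much in 0. Among them Kit had a change of 1.14, Hk2 1.52, Hmga2 0.66, Pou3f1 0.58, Fap −0.71, Gdf15 −0.73, Perp −0.79, Ncmap −0.78, Ntf3 2.95, Hhip 2.88, Cdk4 0.75, Prx −0.87, Pecam1 −0.07 and Abcg1 −2.16.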

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

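The tests of scaling and of glial share, and the use of spike-ins to judge labelling, were chosen only after the result was seen. The number of called genes was 8705 with the animals as blocks; the 4 pairs allow 8 assignments of the media within pairs, too few for a share under 0.05, and the highest count among the other 7 was 0 by limma (137 genes at an unadjusted p under 0.05). Without the block, 1 of the 35 splits of the 8 arrays, the real one, called as many as 8022 genes, the highest of the others was 0 by limma (25 to 3299 at an unadjusted p under 0.05), and chance can be excluded only if the arrays of an animal are taken as independent. Under spike-in scaling 5371 genes stayed called in the same direction, the fewest of 5 scalings. This argues against scaling of the arrays as the whole cause. Labelling that differed by a constant factor per array shifts all genes of an array alike. Subtracting a percentile of each array removes such a factor before the main fit. The count of 5371 therefore cannot test labelling of this kind. A smooth gradient across the slide is argued against by a slope of 0.0272 (95% interval 0.0255 to 0.0289) of the change per slide column, taken between the column pairs, on the change between media, with 1 gene called between the column pairs. Columns 1 and 2 held animals 1 and 3, and columns 3 and 4 held animals 2 and 4. The column pairs therefore also differ in animals, and a gradient offset by differences between animals stays open. The slope of the scanner's fit to the spike-ins was 1.07 and 1.06 on RA-free arrays 3 and 4, against 0.85 to 0.92 on the other arrays. A constant factor per array therefore need not describe the labelling. Labelling that differed between genes or with intensity was not tested. An effect of the medium and an effect of odd or even slide columns stay open, as these cannot be told apart.

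The lower level of the Schwann and satellite glia list may reflect a smaller share of glial cells in RA-free spheres. The 95% intervals of 62.5% of the tested members (10 of 16) left out the list median, where chance gives about 5%. Of these intervals, 5 lay above the median and 5 below it. This argues against a fall of all members by the same factor. A smaller share alone would lower members unequally if other cells also make them, as with Ngfr. The test therefore cannot decide whether a smaller share was the whole cause. The 4 most abundant members with RA, Pmp22 (4.53 ± 0.19, SD, n = 4), Mbp (3.89 ± 0.09), Ngfr (2.58 ± 0.23) and Fabp7 (2.08 ± 0.15), had changes of −0.79, −0.59, −2.39 and −0.99. A smaller share alone stays open. A smaller share together with regulation in single members, a change within the glia, and regulation of these genes in neuroblasts also stay open and were not tested.

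In some groups of 4 arrays 1 array lay far from the other 3, which held for 14 of the 204 groups examined, where chance gives about 1 in 20. In RA-free medium, animal 1 had a level of 2.31 for Rarb against 2.65 to 2.70, of 2.80 for Unc93a against 2.38 to 2.40, and of −1.02 for Ucp2 against −1.70 to −1.64. RA-free animal 3 had 1.48 for Tbx2 against 1.06 to 1.12, and 3.01 for Ddit4 against 3.53 to 3.58. In RA-containing medium, animal 3 had −4.22 for Kit against −3.62 to −3.50, −2.36 for Hmga2 against −3.24 to −3.11, −2.60 for Notch2 against −2.46 to −2.44, and −3.26 for Pecam1 against −3.02 to −2.98. RA-containing animal 1 had 1.32 for Id2 against 1.66 to 1.71, animal 2 had −3.97 for Ntf3 against −3.52 to −3.49, and animal 4 had 2.43 for Chac1 against 2.62 to 2.64. The mean of the adrenocortical list was −0.37 in RA-free animal 2 against −0.45 to −0.44 in the other 3. The 75th percentile of the processed signal was 228 on RA-containing array 3 against 299 to 306 on the other 3. Of 11508 tested probes without a gene name, which enter only the count of all probes, 6006 changed between the media, 4215 higher and 1791 lower in RA-free medium.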

How the results depend on the processing

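Spike-in scaling, median scaling and the fits of animals 1 and 2 or 3 and 4 alone were chosen only after the result was seen. Without the replicate block for the pairing, 8022 genes were called, 7909 of the 8705 kept their call and direction, and no list call changed. The called count was 5463 with spike-in scaling (2027 lower), 2455 with a log2 change of at least 1 added and 16976 of 29355 when all probes were counted, of which 11508 have no gene name and gave 6006 of the calls; 1430 genes changed by at least 1 under normexp with quantile normalization against 2455, and 3238 were higher with animals 1 and 2 alone. Fewer animals, counting every probe, named or not, or a stricter rule explain their own counts. The normexp offset of 50 shrinks changes of dim genes by construction, and its part in the count of 1430 was not tested. Spike-in levels relative to the 75th percentile, RA-free minus RA-containing, were 0.13, 0.27, −0.62 and −0.39 in animals 1 to 4. Spike-in scaling therefore shifts the change of every gene by amounts that differ between animals. The part of these shifts in the count of 5463 was not tested. For the other values the cause was not tested. The median change of all genes, 0.07, was 0.22 with spike-in scaling and −0.04 with the 75th percentile of detected probes; relative to it, the medians of the cell cycle, pan-neuronal and retinoic acid response lists were 1.82, −0.66 and −1.50, which a constant per array cannot alter, but 1.64, −0.80 and −1.46 under normexp with quantile normalization and 1.77, −0.95 and −1.66 under quantile normalization alone. The share of called genes that were higher, 56.1%, ranged from 46.3% to 62.9% over the scalings.

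Medians of lists that were not called changed sign: fibroblast 0.0042 (no filter), 0.063 (spike-in scaling) and 0.058 (animals 3 and 4); immune 0.094 (no filter), 0.022 (array weights) and 0.078 (spike-in scaling); p53 response 0.052 (filter on all 8 arrays); stress 0.012 (mean of probes) and 0.113 (spike-in scaling); endothelial 0.034 (spike-in scaling). Mycn was 0.014 with animals 3 and 4 alone. The mean of the immune list was −0.136 with no filter and −0.186 with the filter on all 8 arrays, and with no filter that of the glial list was −0.412 and that of the fibroblast list −0.039, where other members are tested; the cause of the rest was not tested.

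With each animal left out in turn, 7350 to 8245 genes were called, 4079 to 4663 higher and 3263 to 3582 lower, 2314 to 2617 changed by at least 1, and 5 or 6 lists were called. The immune median ran from −0.240 to 0.036 and the list means from −0.778 to −0.648 (immune), −0.249 to 0.0073 (endothelial), 0.344 to 0.430 (adrenocortical), −0.576 to −0.503 (glia) and −0.260 to −0.107 (fibroblast); the mean correlation between arrays of the same animal ran from 0.227 to 0.413. Of the named genes' values under the alternatives, 1503 kept their direction and side of the threshold, 29 lost their call, 2 gained one and 1 changed sign. A slide or scan block was not run. Signal over background limits what can be said of dim genes.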

Other observations

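The tests of the gene groups and of the Hox neighbours given here were chosen only after the result was seen. Hox genes were lower without RA, with 15 of 20 tested members called lower by limma and a median change of −1.20 (camera adjusted p = 7.52e-07; adjusted p = 0.122 with an estimated correlation, so the call was lost). Besides Hoxb5, Hoxb8 was at least 10.1-fold lower (a change of −1.82, smaller than this bound, under normexp with quantile normalization), Hoxb3 had a change of −3.92 (SE 0.11) and Hoxc8 one of −1.36 (SE 0.07), whereas Hoxd8 (−0.16) did not pass. Genes of MHC class I antigen presentation were lower in 10 of 16 cases and Psmb10 was higher (0.44; not called under spike-in scaling), with a median of −0.89 (camera adjusted p = 0.00214; adjusted p = 0.122 with an estimated correlation, so the call was lost). H2-K1 had a change of −3.53, Nlrc5, an activator of class I genes, −3.04, and B2m, the shared light chain, −2.47; probes of H2 genes can cross-hybridise, so single H2 values are uncertain. Immune and glial cells also make class I genes, and the mean levels of their marker lists were lower too, by 0.72 (0.17 with Aif1 and Adgre1 at their bounds) and 0.54, so a smaller share of these cells stays open and was not tested. Of 16 Polycomb genes 11 were called higher, among them Ezh2 (1.58) and Suz12 (0.92), and 3 lower, among them Ezh1 (−1.10), with a median of 0.65 (camera adjusted p = 0.0345; adjusted p = 0.231 with an estimated correlation, so the call was lost). Spike-in scaling left 10 Polycomb genes higher and 1 lower, and 1 was lower without animal 4. Under normexp with quantile normalization the medians of the class I and Polycomb genes were −0.51 and 0.42 and the change of Psmb10 was 0.26. With the filter on all 8 arrays, the Hox median was −0.80, with 9 of 11 tested members lower.

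Of 12 tested cholinergic genes and neuropeptides, 8 were called lower and 2 higher, with a median of −1.51 (−0.71 with no filter on dim probes and −0.98 with the filter on all 8 arrays; camera adjusted p = 0.0212; adjusted p = 0.181 with an estimated correlation, so the call was lost). Slc18a3, the vesicular acetylcholine transporter, had a change of −4.99 (SE 0.33), Chat, which makes acetylcholine, −3.06 (SE 0.15) and Gal, the galanin precursor, −3.15 (SE 0.19), and Sst was at least 6.5-fold lower. Calca (1.28) and Cartpt (1.54) rose, and Npy (0.73, SE 0.61) did not pass. Among 14 adrenergic and acetylcholine receptors 7 were called lower and 2 higher, with a median of −0.76 (camera adjusted p = 0.0140; adjusted p = 0.198 with an estimated correlation, so the call was lost): the nicotinic subunits Chrnb4 and Chrna3 had changes of −4.83 and −4.21, and Adra2c rose by 3.61. Of 11 immediate early genes 7 were called lower and 2 higher, with a median of −0.57 (camera adjusted p = 0.0274; adjusted p = 0.181 with an estimated correlation, so the call was lost); Fos had a change of −3.12 and Arc −2.40, and 3 were lower under spike-in scaling and 1 higher without animal 2. The 14 neurotrophin and GDNF family ligands and receptors went both ways, 7 higher and 6 lower (camera adjusted p = 0.894), with Bdnf at 2.87, Artn at 1.58, Gfra2 at −2.41 and Ret at −1.43. Under normexp with quantile normalization the receptor median was −0.46, and changes were smaller for Sst (−1.36, short of its bound), Calca (0.47), Chrna3 (−2.81), Fos (−1.85), Arc (−1.18) and Artn (0.81).

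Several genes next to the Hoxa and Hoxb clusters in the gene order of assembly GRCm38.p6 were lower as well, among them Skap2 (−5.92), Skap1 (−4.17) and Copz2 (at least 3.19-fold, with a change of −0.63 under normexp with quantile normalization), so a change may extend from the Hox clusters to their neighbours. Of the 40 tested genes that flank the 4 clusters, 5 on each side, 15 were called lower and 16 higher, such as Cbx3 (0.83, or 0.44 under the same alternative), and their median lay at percentile 28.9 of medians around 10000 random anchors. Of these, 8 (20%, against 10.6% of all tested genes) were lower by at least 1 (Fisher's exact p = 0.0674). Among the 8, Jazf1 (−0.32), Calcoco1 (−0.54), Nfe2 (−0.55) and Copz2 fell by less than 1 under normexp with quantile normalization. Skap2, Skap1, Snx11 and Smug1 still fell by at least 1 under it. For the 20 genes beside Hoxa and Hoxb the median of −0.15 lay at percentile 10.7. Neighbouring genes across the genome resembled each other little (Spearman rho 0.10 across 13100 pairs; at most 0.029 in 1000 shuffles), which leaves a general similarity of neighbours open. Neither test settles the hypothesis, since a change confined to a few flanking genes would barely move these medians.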
